A study of Rattus norvegicus with 6 samples.

How the data were processed

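RNA sequencing of RSC96 cells, an immortalised rat Schwann cell line, was re-analysed from 6 libraries in 3 groups of 2. Per the labels, the groups were PVDF@PDA (hypoxia with a piezoelectric material), PCL@PDA (hypoxia with a non-piezoelectric material) and Control, each with 1 library of batch 1 and 1 of batch 3. Libraries were assigned to groups by their titles and treatment fields, and replicates are called 1 and 3 as in the titles. The free-text field of the PCL@PDA libraries names the other material, and the titles were followed. Total RNA was purified on columns with a DNase step, per the labels.

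The deposited table holds raw read counts per gene in all 6 libraries, whole numbers with totals of 32760123 (PVDF@PDA replicate 1), 33962216 (PVDF@PDA replicate 3), 34460767 (PCL@PDA replicate 1), 33602694 (PCL@PDA replicate 3), 34055444 (Control replicate 1) and 35389307 (Control replicate 3). It lists 16849 genes, each with at least 1 count over the 6 libraries. The deposited tables per library hold FPKM values, which the authors scaled by gene length and by the total of each library. For all 15690 genes counted in at least 2 libraries, the count divided by the FPKM gave a single gene length times the library total, within a relative tolerance of 1e-05. DESeq2 1.4.5 and the rat assembly mRatBN7.2 are named in the submitters' processing notes, without their role. The aligner, the read counter, the annotation and the counting strand are not given in the sources used here. Gene symbols are those of the deposited table. A newer rat annotation (GRCr8) matched 16673 of the gene IDs and served only to find renamed list genes and the genes that adjoin or overlap another one.

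Counts were fitted in edgeR 4.0.16 (R 4.3.3) with TMM scaling, the filter of filterByExpr on the group design and a robust quasi-likelihood fit of the 3 group means over all 6 libraries, which left 3 residual degrees of freedom. The filter kept 13018 genes and removed 3831. Each of the 3 pairs of groups was compared by the 2-sided quasi-likelihood F test, and genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes tested were called. All adjusted p-values below come from this test unless another is named. Levels are TMM-scaled CPM, given as mean ± SD with n = 2, and fold changes are log2 values with their standard error. The biological coefficient of variation was 6.47% and the median prior degrees of freedom were 50.3. A total of 3 counts corresponds to 0.0848 to 0.0916 CPM, so genes near that level could not be resolved at this depth. Intervals of count ratios and this floor cover counting error only.

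The labels do not say that the libraries came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. Libraries of a group were compared by a chi-square of their counts, and none matched another within sampling noise. The labels give batch 1 for replicate 1 and batch 3 for replicate 3 of each group, while the library names number the latter 2, so a fit with the batch as an added term was the main alternative. It left 2 residual degrees of freedom, and its median prior degrees of freedom were infinite. Many genes in that fit thus took their spread from the trend over all genes and not from their own libraries. Deviations from the group mean correlated across genes between libraries of the same batch at r = -0.02 (PVDF@PDA with PCL@PDA), 0.04 (PVDF@PDA with Control) and 0.13 (PCL@PDA with Control).

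Before the data were examined, 30 gene lists, the rule for naming genes, the tests and most alternatives were fixed. The lists cover hypoxia and metabolism, inflammation, Schwann cell state, secreted factors and matrix, stress responses, the cell cycle, lipids, lysosomes, RNA quality and markers of other cell types. Of 769 list genes 725 were in the table, 9 of them under another symbol, and 29 lists had at least 3 tested members. The list of mitochondrially encoded genes was not analysed here. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists, and again with an estimated correlation and with the directional fry test (limma 3.58.1). Members past the test were also counted with p-values adjusted over the list alone.

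Genes were named by this rule. In each comparison they were the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 1, a symbol that is not a locus identifier and the same direction in both batches. Added to these were up to 4 members with the smallest p of each list described, and the fixed genes Vegfa, Slc2a1, Bnip3, Ca9, Sox10, S100b, Ngfr, Jun, Piezo1 and Hmox1. Sox10 was not analysed here. Ngfr (0 to 4 counts per library) had too few counts to be tested. Some genes covered by this rule are not reported here. Lrrc39 and LOC120094192, as well as the replication genes Mcm3, Mcm7 and Cdc6, fell outside the rule and were chosen after their values were seen, as were the values of Mmp13 and Slc24a5 against Control and the list members Stc2, Cxcl10, Csf1, Gabarapl1, Nqo1, Slc7a11, Oasl and Bst2, which moved against their lists.

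The overlap of the 2 material comparisons with Control was set against 40 simulations of unchanged groups with a shared control and against the product of the list sizes. The tests were tried on simulated data in which 50 genes per fold were changed between groups drawn with the gene dispersions seen here. For PVDF@PDA against PCL@PDA, the edgeR test recovered 46% of genes changed 1.25-fold, 64% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 7 false calls. For PVDF@PDA against Control the shares were 52%, 76%, 98% and 98% with 5 false calls, and for PCL@PDA against Control 38%, 60%, 82% and 100% with 14 false calls. The list of hypoxia-induced genes, shifted 1.25-fold, was called by camera with either correlation and by fry in each comparison. The simulated genes were drawn independently, whereas this list had an estimated correlation of 0.31 to 0.33 in the data. That trial therefore does not show the power for lists of correlated genes.

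Alternatives were the batch as an added term, DESeq2 1.42.0, RLE size factors, library totals only, no filter on low counts, a mean of at least 1 CPM, only the 4 libraries compared, a log2 fold change of at least 1 as well, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1, and each library left out in turn. A non-robust fit, removal of the trend with gene length and their combinations with the batch term, the batch term in DESeq2, the overlap of fold changes that share no library and the enrichment of KEGG pathways, with and without the members of the gene lists, were added after seeing the data. With groups of 2, splits of the samples into other groups were not tested. Effects of GC content were not tested. Python 3.11.15 was used for the tables and plots.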

Results

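Transcript levels were measured in RSC96 Schwann cells under 3 conditions with 2 libraries each, and 32760123 to 35389307 reads were counted per library. Cells had been kept for 24 h in a hypoxia model based on medium conditioned by macrophages, together with a piezoelectric (PVDF@PDA) or a non-piezoelectric (PCL@PDA) material. The labels do not state whether the Control cells received that medium, so differences from Control are differences between whole conditions. Eef1a1, a translation elongation factor, was the most abundant gene and took 0.89% to 0.98% of the counts. The first principal component (34.5% of the variance) placed the Control libraries at 27.6 and 29.3 and the 4 material libraries between -15.2 and -13.0. On the second component (20.8%) PCL@PDA replicate 3, at -28.5, stood apart from PCL@PDA replicate 1 at 6.09. The counts of the PVDF@PDA pair differed by a chi-square of 4.86 per degree of freedom, those of the Control pair by 5.65 and those of the PCL@PDA pair by 10.6. Replicate 1 of PVDF@PDA and replicate 1 of PCL@PDA differed by 4.47, and material libraries differed from Control libraries by 22 to 37.2. Among macrophage markers, the leukocyte antigen Ptprc lay at 0 to 0.0283 CPM of library totals. Coro1a lay at 1.61 to 1.97 in the material libraries and at 0.881 and 0.819 in Control. Cd14 lay the other way, at 4.53 to 5.09 in the material libraries and 5.78 and 6.02 in Control.

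**Figure D1:**
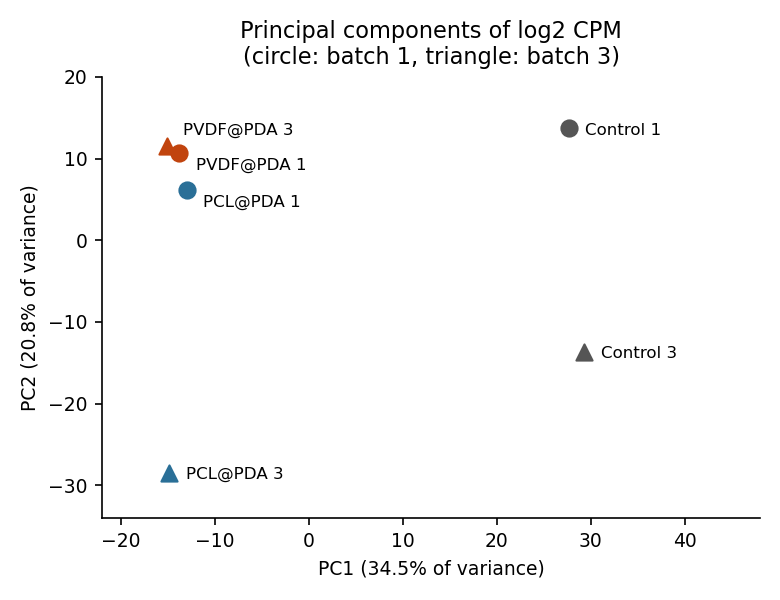
Principal component scores of the 6 libraries from log2 CPM of 13018 genes, with the share of variance on each axis. Control lies at 27.6 and 29.3 on the first component, the 4 material libraries lie between -15.2 and -13.0, and PCL@PDA replicate 3 lies at -28.5 on the second.

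Whether the piezoelectric material changes Schwann cells under hypoxic stress is the question of PVDF@PDA against PCL@PDA, and few genes differed. Best1, a calcium-activated chloride channel (gene ID 293735), was higher with PVDF@PDA at 11.4 ± 4.53 CPM against 4.63 ± 0.525 (log2 1.30, SE 0.21, adjusted p = 0.00205). Slc24a5, a cation exchanger of pigment organelles (gene ID 311387), was higher at 4.55 ± 2.19 against 1.64 ± 0.133 (log2 1.47, SE 0.30, adjusted p = 0.0263). Cacna2d4, an auxiliary subunit of voltage-gated calcium channels (gene ID 312668), was higher at 9.58 ± 3.88 against 4.44 ± 0.753 (log2 1.11, SE 0.22, adjusted p = 0.0263). Mmp13, a collagenase (gene ID 171052), was higher at 262 ± 14.9 against 214 ± 2.96, with 342 ± 7.43 in Control (log2 0.29, SE 0.05, adjusted p = 0.00714). The WD-repeat gene Wdr38 (gene ID 366035) was higher at 73.6 ± 3.35 against 52.3 ± 8.55 (log2 0.49, SE 0.08, adjusted p = 0.00205). Slc39a13, a zinc transporter (gene ID 295928), was lower at 44.3 ± 1.55 against 57.3 ± 1.43 (log2 -0.37, SE 0.08, adjusted p = 0.0354). Of 13018 genes tested by edgeR's quasi-likelihood test, 8 passed, 7 higher and 1 lower, each in the same direction in both batches, and 1105 had an unadjusted p below 0.05. The other 2 were chosen after their values were seen and had few reads. LOC120094192 had 17 and 75 counts against 3 and 2, a ratio of 18.9 with a counting interval of 7.79 to 59.4 (adjusted p = 0.0127). Lrrc39 had 54 and 80 counts against 10 and 14, a ratio of 5.72 with a counting interval of 3.69 to 9.24 (adjusted p = 0.0263). Cacna2d4, Slc24a5, Wdr38 and Lrrc39 overlap another tested gene and Best1 adjoins the abundant Fth1, while the counting strand was not given. With the batch as an added term 59 genes passed, 17 higher and 42 lower, and these included all 8. With that term in DESeq2 15 passed, 3 higher and 12 lower, with Mmp13 alone of the 8, as the tool's filter on mean counts kept 2149 genes and removed the other 7 (unadjusted p = 2.88e-06 for Wdr38 to 0.000594 for Cacna2d4).

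The calls depended on which libraries were included. Without PVDF@PDA replicate 3, edgeR called 0 genes, with 722 at an unadjusted p below 0.05, and DESeq2 also called 0 with 278. The adjusted p was then 0.816 for Best1, 0.918 for Slc24a5 and Cacna2d4, 0.142 for Wdr38, 0.867 for Mmp13, 0.370 for Slc39a13, 0.755 for Lrrc39 and 0.903 for LOC120094192. The log2 difference was then 0.44 for Wdr38, -0.41 for Slc39a13, 0.23 for Mmp13 and 2.22 for Lrrc39, close to the values with all libraries, and smaller for Best1 (0.82), Slc24a5 (0.87), Cacna2d4 (0.62) and LOC120094192 (2.77). Without PCL@PDA replicate 3, which stood apart, 2 genes passed, and the adjusted p was 0.510 for Cacna2d4, 0.309 for Slc24a5, 0.243 for Slc39a13 and LOC120094192, 0.160 for Wdr38 and 0.152 for Lrrc39. The log2 differences of these genes were 0.95, 1.39, -0.35, 3.91, 0.34 and 2.77 in that order. Without PVDF@PDA replicate 1, 10 genes passed and Slc39a13 did not (adjusted p = 0.416). Without PCL@PDA replicate 1 the count was 827, and without either Control library it was 13. DESeq2 called 5 genes, not Slc24a5 and Cacna2d4 (both 0.229) or Slc39a13 (0.0988), and scaling by library totals alone also left 5, without Slc24a5 and Slc39a13 (both 0.0639) and Cacna2d4 (0.0717). With limma on log2(FPKM + 1) or log2(FPKM + 0.1), 0 genes passed, with 837 and 829 at an unadjusted p below 0.05. Groups simulated as unchanged gave 1.58 calls on average and at most 6. All simulated libraries had the same dispersion per gene, so none stood apart as PCL@PDA replicate 3 did. These values therefore give no chance level for calls that depend on such a library.

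**Figure D2:**
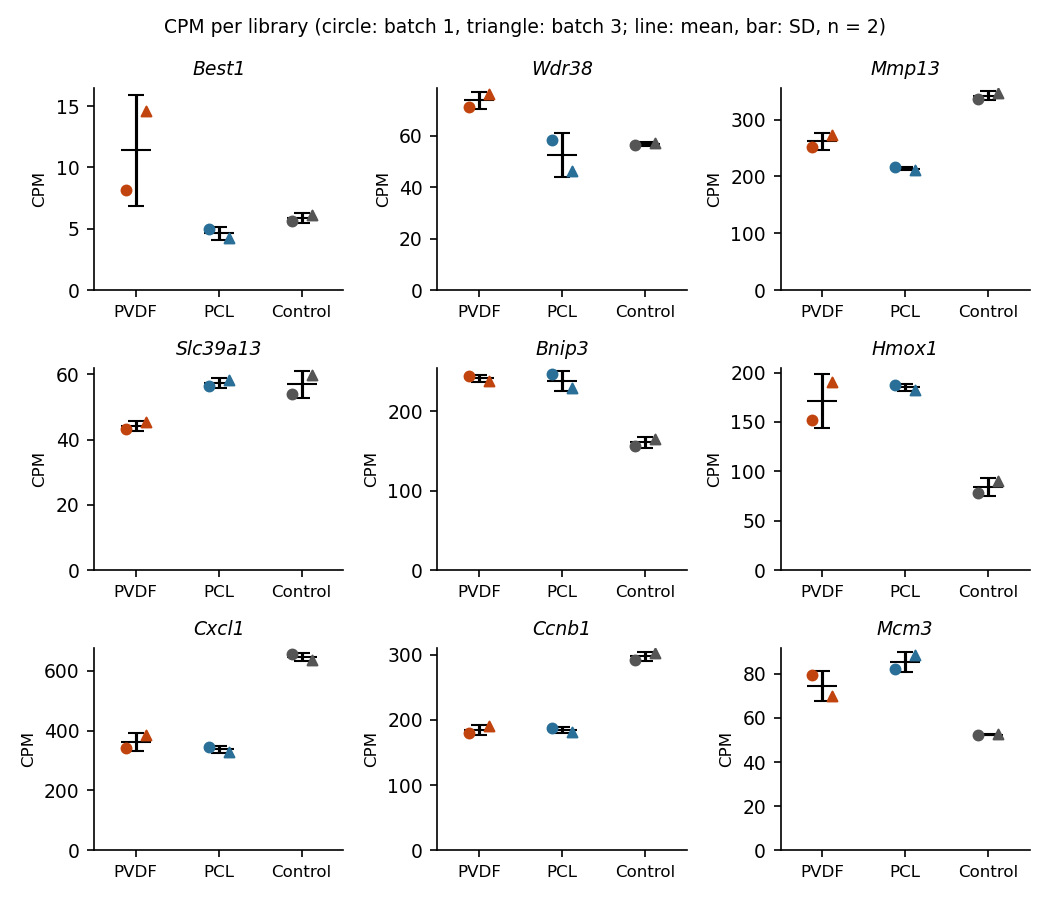
CPM of 9 genes in each library, with the group means and the SD of 2 libraries as error bars. Best1 lies at 11.4 with PVDF@PDA and 4.63 with PCL@PDA, while Bnip3 and Hmox1 lie higher and Cxcl1 and Ccnb1 lower with both materials than in Control.

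The hypoxia readouts lay close together in the material groups. The log2 difference between PVDF@PDA and PCL@PDA was 0.01 for the growth factor Vegfa (95% interval -0.09 to 0.11), 0.02 for the mitophagy receptor Bnip3 (-0.09 to 0.14) and -0.02 for the carbonic anhydrase Ca9 (-0.67 to 0.62). It was -0.15 for the glucose transporter Slc2a1 (-0.27 to -0.04, adjusted p = 0.424, and 0.00314 without PCL@PDA replicate 1). The difference was 0.02 for the injury-induced transcription factor Jun (-0.10 to 0.14) and -0.11 for the heme oxygenase Hmox1 (-0.30 to 0.08). The mechanosensitive channel Piezo1 differed by -0.10 (-0.23 to 0.02), and by -0.22 without PCL@PDA replicate 1 (adjusted p = 0.0106). S100b, a Schwann cell marker, lay below 0.5 CPM in each group mean, and its interval ran from -1.02 to 2.53. Over all genes, the 95% interval of the difference lay within 0.5 log2 of 0 for 8999 of 13018 genes and within 1 log2 for 10930.

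Between the materials, 5 of 29 gene lists were lower with PVDF@PDA by camera, with small shifts and no member called over all genes. They were the NRF2 antioxidant genes (23 tested, 3 lower adjusted over the list alone, adjusted p = 0.00450), the glycolytic enzymes (16 tested, 1 lower adjusted over the list alone, 0.00829), the cytosolic ribosomal proteins (51 tested, 5 lower adjusted over the list alone, 0.0115), the ATF4 amino acid response (28 tested, 0 adjusted over the list alone, 0.0171) and the lysosome and autophagy genes (29 tested, 0 adjusted over the list alone, 0.0477). None held with an estimated correlation (adjusted p = 0.718 with an estimated correlation for glycolysis and 0.620 for each of the other four), and fry called 0 lists. With the batch as an added term, named members passed over all genes. Lower in these lists were the ferritin chain Ftl1 (adjusted p = 0.000276), the enolase Eno1 (0.0197), the transketolase Tkt (0.0386), the glycine transporter Slc6a9 (0.0386) and the ribosomal Rplp0 (0.00811), Rpl13 and Rpl18 (both 0.0163) and Rplp1 (0.0448). In other lists the collagen crosslinking enzyme Loxl1 (0.000177), the transcriptional regulator Id1 (0.0261), the respiratory chain subunit Uqcrq and the helicase subunit Mcm5 (both 0.0386) were lower and the protease Mmp10 (0.0386) higher with that term. Of these 13 genes only Ftl1 and Loxl1 also passed in each of the variants of the batch fit, with the length trend removed (0.0187 and 0.00138), non-robust (0.00207 and 0.00513) and in DESeq2 with its filter (2.58e-05 and 0.00151). Without PCL@PDA replicate 1 all but Mmp10 passed, from 3.77e-08 for Loxl1 to 0.00424 for Tkt, and Loxl1 also passed without Control replicate 1 (0.0269) or Control replicate 3 (0.0167). Without PVDF@PDA replicate 1 no list was called (adjusted p = 0.210 for NRF2 and lysosome, 0.0549 for glycolysis and ATF4, 0.186 for ribosomal proteins). Without PCL@PDA replicate 3 the values were 0.506 for glycolysis, 0.544 for ATF4 and 0.610 for lysosome. Without PVDF@PDA replicate 3 they were 0.108 for ATF4 and 0.0619 for lysosome, without PCL@PDA replicate 1 0.0557 for ribosomal proteins, and without Control replicate 1 0.0602 for lysosome, which was at 0.0565 with RLE size factors. Lists called lower only with a library left out were the immediate-early genes without PCL@PDA replicate 1 (0.00564) and the cell cycle genes without PCL@PDA replicate 3 (0.0357). The median log2 difference of the called lists lay between -0.07 and -0.02. The hypoxia-induced genes had 0 of 29 members called over all genes or adjusted over the list alone (camera 0.972). The matrix proteases had 1 of 22 higher, Mmp13, and 2 adjusted over the list alone (camera 0.211). In the other 22 lists no member passed over all genes and the camera adjusted p ran from 0.0743, for the respiratory chain, to 0.995, for fatty acid and lipid handling. Adjusted over the list alone, 1 p53 target was higher and 2 were lower, and 1 member was lower in each of the respiratory chain, immature Schwann cell, extracellular matrix, TGF-beta and cell cycle lists. The median, the mean and the camera direction differed in sign in the hypoxia, immature Schwann cell, neurotrophic, extracellular matrix, TGF-beta, heat shock, p53, fatty acid, macrophage, fibroblast and endothelial lists, none of which was called.

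Against Control, many genes differed with PVDF@PDA and its hypoxia model, and genes of inflammation were among the largest falls. Ppargc1a, a coactivator of mitochondrial biogenesis, rose to 3.95 ± 0.0460 CPM from 1.03 ± 0.00932 (log2 1.94, SE 0.32, adjusted p = 7.09e-06). The retinol dehydrogenase Rdh5 rose to 6.33 ± 0.238 from 1.89 ± 0.770 (log2 1.73, SE 0.25, adjusted p = 6.77e-07), and the adhesion protein gene Flrt1 to 7.26 ± 0.515 from 2.43 ± 0.470 (log2 1.58, SE 0.22, adjusted p = 3.83e-07). Mx2, an interferon-induced GTPase, fell to 1.97 ± 0.0123 from 7.27 ± 1.31 (log2 -1.88, SE 0.26, adjusted p = 2.86e-07), the cytokine Il1a to 2.06 ± 0.554 from 6.94 ± 0.280 (log2 -1.75) and the chemokine Cxcl6 to 27.4 ± 0.0209 from 64.4 ± 1.11 (log2 -1.23, SE 0.09, adjusted p = 6.14e-16). In all, 2042 of 13018 genes passed edgeR's quasi-likelihood test, 884 higher and 1158 lower, all in the same direction in both batches, with a median size of 0.34 log2 and 139 genes at 1 log2 or more. Further named rises were the intermediate filament Nes (1.69), Tbc1d16 (1.63), the complement component C3 (1.53), the tau gene Mapt (1.38) and Mia (1.34). Further named falls were the helicase Pif1 (-1.59), the vascular ligand Angpt1 (-1.32), the LIM protein gene Csrp3 (-1.23), Gpatch3 (-1.20) and the guanylate-binding Gbp5 (-1.19). The call of C3 ended without Control replicate 3 (1.05, adjusted p = 0.0656), and those of Mia (1.06, 0.0821) and Csrp3 (-0.85, 0.0758) ended without PVDF@PDA replicate 3. The count was 1184 without PVDF@PDA replicate 1, 1031 without PVDF@PDA replicate 3, 1085 without Control replicate 1 and 1267 without Control replicate 3, and scaling by library totals alone turned the split to 1164 higher and 879 lower.

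In PCL@PDA against Control, Rdh5 rose to 5.77 ± 0.847 CPM from 1.89 ± 0.770 (log2 1.60, SE 0.25, adjusted p = 2.91e-06) and Ppargc1a to 3.11 ± 0.349 (log2 1.60, SE 0.32, adjusted p = 0.000163). The flow-responsive transcription factor Klf2 rose to 4.48 ± 0.892 from 1.60 ± 0.0536 (log2 1.48, SE 0.29, adjusted p = 0.000137), and the vasoactive peptide Adm to 20.6 ± 4.63 from 8.71 ± 2.82 (log2 1.24, SE 0.17, adjusted p = 8.89e-06). Mx2 fell to 1.41 ± 0.0706 (log2 -2.36, SE 0.27, adjusted p = 1.69e-09) and Cxcl6 to 22.8 ± 1.30 (log2 -1.50, SE 0.09, adjusted p = 3.72e-19). Here 2616 genes passed, 1142 higher and 1474 lower, all in the same direction in both batches, with a median size of 0.32 log2 and 145 genes at 1 log2 or more. Flrt1 rose to 6.42 ± 0.205. Further named rises were Nkpd1 (1.32), the matrix protein gene Vwa1 (1.30) and Nes (1.24), and further falls were Il1a (-1.69), Angpt1 (-1.48), Gbp5 (-1.39), Pif1 (-1.39), Flacc1 (-1.30) and the actin-severing Scin (-1.20). The call of Nkpd1 ended without PCL@PDA replicate 3 (0.97, adjusted p = 0.123), that of Nes without PCL@PDA replicate 3 (1.06, 0.0864) or Control replicate 1 (1.11, 0.0831), and that of Scin without Control replicate 3 (-0.80, 0.0890). The count was 1346 without Control replicate 1, and scaling by library totals alone turned the split to 1482 higher and 1070 lower.

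Hypoxia-induced genes were higher with both materials than in Control. Of 29 tested, 17 rose and 1 fell with PVDF@PDA (18 and 1 adjusted over the list alone) and 16 rose and 1 fell with PCL@PDA (17 and 1 adjusted over the list alone). The camera adjusted p was 4.33e-16 and 7.83e-14, with adjusted p = 0.292 and 0.268 with an estimated correlation. Bnip3 rose to 242 ± 4.13 CPM with PVDF@PDA and 238 ± 12.6 with PCL@PDA from 161 ± 7.04 (log2 0.59 and 0.56, SE 0.06, adjusted p = 1.38e-11 and 3.54e-11). The mitochondrial protein gene Higd1a rose by 0.74 and 0.66, the glucose transporter Slc2a3 by 0.39 and 0.45, and Slc2a1 by 0.30 and 0.45. The member that fell was the secreted hormone Stc2 (-0.30 and -0.29), singled out after its values were seen. Its call ended without Control replicate 1 (adjusted p = 0.126 and 0.118), without Control replicate 3 (0.0992 and 0.0821) and, with PVDF@PDA, without PVDF@PDA replicate 3 (0.281), and with scaling by library totals alone (0.0533 and 0.0530). Vegfa rose by 0.16 and 0.15 (adjusted p = 0.0249 and 0.0294), and these calls ended without any single library of PVDF@PDA or Control (0.141 to 0.211 and 0.0635 to 0.232), the second also when only the 4 libraries compared were fitted (0.0625). Ca9 lay at 72.6 ± 5.91 and 73.8 ± 6.88 against 45.4 ± 12.7 and did not pass (log2 0.68 and 0.70, adjusted p = 0.169 and 0.143). With the batch as an added term it passed (7.67e-19 and 2.81e-20), in a fit with infinite median prior degrees of freedom. Without that term, Ca9 passed in a non-robust edgeR fit (1.24e-06 and 4.42e-07) and in edgeR with no filter on low counts (0.000339 and 0.000175). It passed with limma on log2(FPKM + 1) (0.0254 and 0.0173) and, with PCL@PDA, in DESeq2 (0.0325). It also passed without Control replicate 1 (log2 0.42 and 0.44, adjusted p = 0.000975 and 0.000374) and without Control replicate 3 (0.99 and 1.02, 2.12e-16 and 2.38e-17).

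Glycolytic enzymes rose in 9 of 16 genes with PVDF@PDA and 12 of 16 with PCL@PDA, and none fell (9 and 13 adjusted over the list alone). The camera adjusted p was 2.44e-07 and 6.54e-11, with adjusted p = 0.474 and 0.376 with an estimated correlation. The lactate dehydrogenase Ldha rose to 1199 ± 3.80 and 1240 ± 1.65 CPM from 908 ± 44.5 (log2 0.40 and 0.45), Tpi1 rose by 0.36 and 0.42 and Gpi by 0.38 and 0.41. Nuclear-encoded respiratory chain subunits did not move as a list (4 and 7 of 42 members past the test, 3 and 5 adjusted over the list alone, camera 0.850 and 0.576).

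Inflammatory genes were lower with both materials. Of 30 inflammatory cytokines and NF-kB targets, 19 fell and 2 rose with either material (20 and 2 adjusted over the list alone), with a camera adjusted p of 9.82e-19 and 1.01e-17 and adjusted p = 0.0858 and 0.101 with an estimated correlation. The chemokine Cxcl1 fell to 362 ± 30.8 and 337 ± 12.3 CPM from 647 ± 14.2 (log2 -0.84 and -0.94, SE 0.05, adjusted p = 2.38e-17 and 3.04e-19). The inhibitor Nfkbia changed by -0.79 and -0.78 and the subunit Nfkb1 by -0.74 and -0.66. The members that rose were the chemokine Cxcl10 (0.48 and 0.45) and the growth factor Csf1 (0.22 and 0.22), singled out after their values were seen, and the call of Csf1 with PVDF@PDA ended without PVDF@PDA replicate 3 (adjusted p = 0.0522). Of 31 genes of the type I interferon response, 14 fell and 0 rose with PVDF@PDA (16 and 2 adjusted over the list alone) and 12 fell and 2 rose with PCL@PDA (13 and 2 adjusted over the list alone). The camera adjusted p was 2.15e-10 and 9.87e-08, with adjusted p = 0.0858 and 0.101 with an estimated correlation. The guanylate-binding Gbp2 fell to 263 ± 1.71 and 258 ± 13.6 from 473 ± 5.95 (log2 -0.85 and -0.87), and Parp14 changed by -0.67 and -0.64. With PCL@PDA, Bst2 rose by 0.27 and Oasl by 0.24, genes singled out after their values were seen, and both calls ended without PCL@PDA replicate 3 (adjusted p = 0.268 and 0.358) or Control replicate 1 (0.117 and 0.239). The STAT3 and gp130 targets did not move as a list (2 of 15 higher and 3 lower with either material, 3 and 3 with PVDF@PDA and 2 and 3 with PCL@PDA adjusted over the list alone, camera 0.735 and 0.911).

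**Figure D3:**
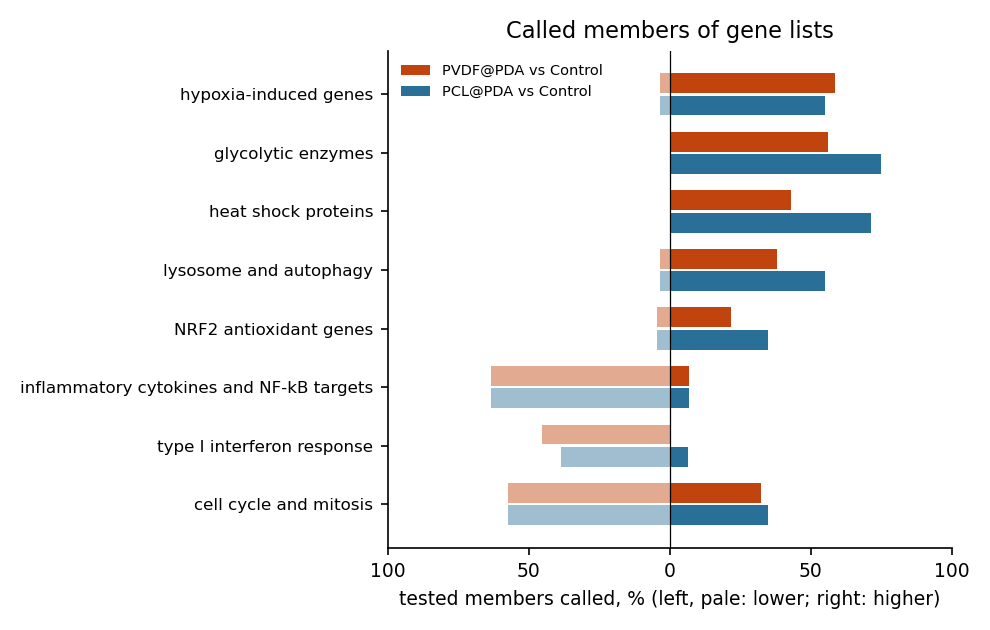
Share of tested members called higher and lower over all genes in selected gene lists, for PVDF@PDA and PCL@PDA each against Control, in percent. Against Control, 19 of 30 inflammatory genes are lower and 17 (PVDF@PDA) or 16 (PCL@PDA) of 29 hypoxia-induced genes higher.

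Heat shock proteins rose in 6 of 14 genes with PVDF@PDA and 10 of 14 with PCL@PDA, and none fell over all genes (7 and 0, and 10 and 1, adjusted over the list alone). The camera adjusted p was 5.89e-08 and 1.48e-07, with adjusted p = 0.0858 and 0.101 with an estimated correlation. The chaperone Hspa8 rose to 1239 ± 17.0 and 1343 ± 33.6 CPM from 734 ± 13.9 (log2 0.75 and 0.87, SE 0.05), Hsph1 by 0.74 and 0.74 and Hspb8 by 0.31 and 0.30. Of 23 NRF2 antioxidant genes, 5 rose and 1 fell with PVDF@PDA (5 and 2 adjusted over the list alone, camera 0.0512, called without PVDF@PDA replicate 1 at 0.0158, without Control replicate 3 at 0.0135, with RLE size factors at 0.0485 and when scaled by library totals alone at 0.0364). With PCL@PDA 8 rose and 1 fell (9 and 1 adjusted over the list alone), with a camera adjusted p of 0.000116 and adjusted p = 0.268 with an estimated correlation. Hmox1 rose to 171 ± 27.7 and 185 ± 3.53 from 84.2 ± 8.67 (log2 1.02 and 1.14, SE 0.09, adjusted p = 8.11e-07 and 1.8e-07). These calls ended without PCL@PDA replicate 1 (0.0627 and 0.0670) or PCL@PDA replicate 3 (0.0681 and 0.0936), and the first also when only the 4 libraries compared were fitted (0.0628). The peroxiredoxin Prdx1 rose by 0.35 and 0.27 and Ftl1 by 0.40 and 0.61. The members that fell, singled out after their values were seen, were the quinone reductase Nqo1 with PVDF@PDA (-0.19) and the cystine transporter Slc7a11 with PCL@PDA (-0.18). Nqo1 did not pass without PVDF@PDA replicate 1 (adjusted p = 0.428), Control replicate 1 (0.0641) or Control replicate 3 (0.241), nor Slc7a11 without PCL@PDA replicate 3 (0.0638) or Control replicate 1 (0.268), and neither passed with scaling by library totals alone (0.0780 and 0.0588). Neither the ATF4 amino acid response (9 and 7 of 28 past the test, 9 and 8 adjusted over the list alone, camera 0.180 and 0.972) nor the endoplasmic reticulum chaperones (2 and 5 of 20, 1 and 9 adjusted over the list alone, camera 0.241 and 0.151) was called, though the chaperones were lower with PCL@PDA without PCL@PDA replicate 1 (0.0216).

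Lysosome and autophagy genes rose in 11 of 29 genes with PVDF@PDA and 16 of 29 with PCL@PDA, and 1 fell with each (14 and 1, and 18 and 2, adjusted over the list alone). The camera adjusted p was 0.000454 and 3.17e-06, with adjusted p = 0.292 and 0.245 with an estimated correlation. The autophagosome protein gene Map1lc3b rose by 0.38 and 0.44, and the cathepsins Ctsb and Ctsd by 0.28 each with PCL@PDA. The member that fell was the autophagy gene Gabarapl1 (-0.24 and -0.19), singled out after its values were seen, and its call with PCL@PDA ended without Control replicate 1 (adjusted p = 0.140).

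Genes of cell division split into falls and rises. Of 40 cell cycle genes, 23 fell and 13 rose with PVDF@PDA (24 and 14 adjusted over the list alone) and 23 fell and 14 rose with PCL@PDA (23 and 15 adjusted over the list alone). The list was called lower, with a camera adjusted p of 4.61e-08 and 2.68e-05 and adjusted p = 0.284 and 0.268 with an estimated correlation. The members that fell act in mitosis, among them the mitotic cyclin Ccnb1, which fell to 185 ± 7.58 and 185 ± 4.73 CPM from 297 ± 7.25 (log2 -0.69 and -0.69, SE 0.06, adjusted p = 3.59e-14 and 2.51e-14). The spindle protein gene Prc1 changed by -0.61 and -0.68 and the topoisomerase Top2a by -0.52 and -0.60. Members that rose act in DNA replication, and the examples Mcm3 (0.51 and 0.71), Mcm7 (0.54 and 0.68) and Cdc6 (0.68 and 0.69), which load or form the replicative helicase, were chosen after their values were seen. Of 18 p53 targets, 4 fell with PVDF@PDA (5 adjusted over the list alone), with a camera adjusted p of 0.0341 and adjusted p = 0.376 with an estimated correlation, and 0.0541 when scaled by library totals alone. With PCL@PDA 5 fell (7 lower and 1 higher adjusted over the list alone, camera 0.0981, and 0.00343 without PCL@PDA replicate 3). The death receptor Fas changed by -0.61 and -0.75 and the antiproliferative gene Btg2 by -0.50 and -0.46.

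Single genes of Schwann cell state and secreted factors changed, while camera called none of their lists. Tnc, a matrix glycoprotein of the immature and repair Schwann cell list, fell to 812 ± 27.8 and 832 ± 38.6 CPM from 1437 ± 54.8 (log2 -0.82 and -0.79, SE 0.05, adjusted p = 1.08e-18 and 2.33e-18), and Runx2 changed by -0.28 and -0.30. In that list 8 and 9 of 18 members passed (9 and 11 adjusted over the list alone, camera 0.419 and 0.607). Jun rose by 0.23 and 0.22 (adjusted p = 0.00297 and 0.00526). Its call ended without Control replicate 3 (0.0731 and 0.0854) and, with PVDF@PDA, without PVDF@PDA replicate 1 (0.119). Of the myelin and Schwann cell differentiation genes 3 of 11 passed with either material (3 and 5 adjusted over the list alone, camera 0.850 and 0.956). S100b lay at 0.496 ± 0.372 and 0.292 ± 0.331 against 0.477 ± 0.513 CPM and did not pass. Among 14 neurotrophic factors 4 and 5 passed (5 and 5 adjusted over the list alone, camera 0.0685 and 0.130), with Lif at -0.63 and -0.76 and the glial factor Gdnf at -0.43 and -0.44. The neurotrophic list was lower with PCL@PDA by fry (adjusted p = 0.0460), and with PVDF@PDA by camera without Control replicate 1 (0.0418). Of 30 genes of the extracellular matrix and basal lamina, 13 and 11 passed (13 and 12 adjusted over the list alone, camera 0.839 and 0.956). The collagen genes Col5a2 (-0.43 and -0.41) and Col1a1 (0.68 and 0.71) moved apart. Piezo1 was at 156 ± 1.51 CPM with PVDF@PDA (log2 0.09, adjusted p = 0.365) and rose to 168 ± 19.5 with PCL@PDA from 147 ± 2.99 (0.19, adjusted p = 0.0209). That call ended without PCL@PDA replicate 3 (0.07, adjusted p = 0.542), Control replicate 1 (0.21, 0.0697) or Control replicate 3 (0.17, 0.148). The mechanosensitive and calcium channels did not move as a list (5 and 7 of 27 past the test, 7 and 7 adjusted over the list alone, camera 0.679 and 0.408).

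Lipid genes included the change with the smallest p in both comparisons with Control. The stearoyl-CoA desaturase Scd2 fell to 257 ± 3.34 and 255 ± 8.71 CPM from 507 ± 19.2 (log2 -0.98 and -0.99, SE 0.05, adjusted p = 8.8e-21 and 5.55e-21), and the sterol exporter Abcg1 changed by -0.87 and -0.80. The mitochondrial fatty acid importer Cpt1a rose to 46.1 ± 3.72 and 46.3 ± 1.51 from 25.0 ± 0.0467 (log2 0.88 and 0.89). As a list, fatty acid and lipid handling did not move (7 of 23 higher and 5 lower with PVDF@PDA, 5 and 5 with PCL@PDA, 7 and 6 with either adjusted over the list alone, camera 0.839 and 0.956). Of 24 cholesterol synthesis genes 6 fell and 1 rose with either material (7 lower and 1 higher with PVDF@PDA and 6 and 4 with PCL@PDA adjusted over the list alone, camera 0.199 and 0.689), with Insig1 at -0.48 and -0.45 and the regulator Srebf2 at -0.38 and -0.33. The median, the mean and the camera direction differed in sign, with PVDF@PDA, in the myelin, immature Schwann cell, fatty acid and endothelial lists. With PCL@PDA they differed in the immature Schwann cell, fatty acid, endothelial, ribosomal, protease, YAP/TAZ, ATF4 and cholesterol lists.

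The remaining lists were not called against Control. Members past the test numbered 13 and 17 of 30 immediate-early genes (14 and 19 adjusted over the list alone, camera 0.592 and 0.151, with PCL@PDA higher at 0.0158 without PCL@PDA replicate 1), 6 and 8 of 22 matrix proteases and inhibitors (8 and 8, 0.679 and 0.956), 6 and 7 of 18 YAP/TAZ targets (7 and 8, 0.338 and 0.956) and 4 and 2 of 18 TGF-beta and BMP targets (4 and 2, 0.464 and 0.408). Of 51 cytosolic ribosomal proteins, 6 passed with either material (5 and 6 adjusted over the list alone, camera 0.183 and 0.972), and with PVDF@PDA the list was lower without Control replicate 1 (0.0415). Among markers of other cell types, 0 of 7 macrophage genes passed edgeR's test with either material (3 and 0 adjusted over the list alone, camera 0.464 and 0.646). Of 7 fibroblast genes 3 and 4 passed (4 and 4, 0.942 and 0.972), and of 4 endothelial genes 0 and 1 (0 and 1, 0.942 and 0.972). Prrx1, a fibroblast marker, fell to 98.0 ± 2.79 and 89.8 ± 1.42 CPM from 164 ± 2.87 (log2 -0.74 and -0.87), while Pdgfra rose by 0.65 and 0.57. Neuron markers were called higher with PVDF@PDA (2 of 8 over all genes and over the list alone, camera 0.0341, adjusted p = 0.320 with an estimated correlation) and not with PCL@PDA (2 of 8, camera 0.160). That call ended without PVDF@PDA replicate 3 (0.0949), PCL@PDA replicate 1 (0.0515) or Control replicate 3 (0.142) and when scaled by library totals alone (0.0523). The neurofilament Nefh rose to 36.4 ± 0.487 and 34.9 ± 1.59 from 21.4 ± 2.19 (log2 0.76 and 0.70).

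The materials shared many of their calls against Control. Both comparisons called 609 genes higher and 910 lower, with 0 in opposite directions, where independent lists would share 77.5 and 131. The shared Control libraries alone produce a correlation, since simulated unchanged groups had one of 0.50 across genes. They had 0.175 and 0.225 shared calls on average, but only 1.775 and 1.65 calls in each comparison with Control. They thus cannot show how many of the 609 and 910 shared calls come from the shared controls. The observed correlation of log2 fold changes across genes, which are not independent replicates, was 0.72, and the covariance of 0.150 exceeded the simulated one by 0.117. Fold changes between single libraries, which are noisier than those of group means, correlated at 0.32 both ways when they shared no library. Their covariance was then 0.077 both ways. With a shared Control library such fold changes correlated at 0.66 (batch 1) and 0.60 (batch 3), with covariances of 0.151 and 0.153. Part of the excess may still come from the shared controls, as 2 Control libraries cannot be divided into separate sets of 2. The shared count was 959 without PVDF@PDA replicate 1, 876 without PVDF@PDA replicate 3, 797 without Control replicate 1 and 1001 without Control replicate 3.

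**Figure D4:**
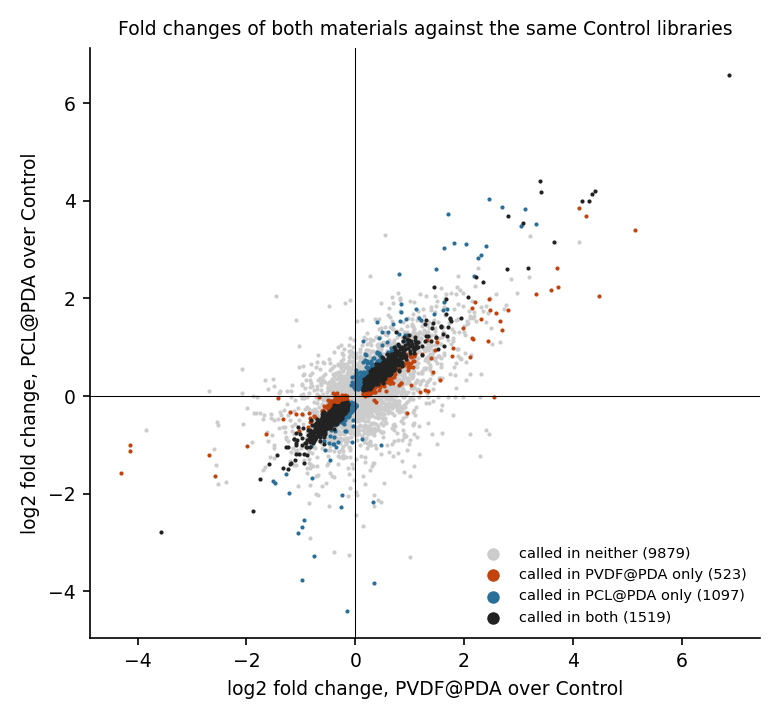
Log2 fold change against Control of 13018 genes with PVDF@PDA and with PCL@PDA. Points follow the diagonal, 1519 genes are called in both comparisons and 0 of these lie in opposite directions.

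Of the 8 genes called between the materials, 4 had been called in the opposite direction between PCL@PDA and Control, and 0 in the same direction. Mmp13 was lower in PCL@PDA than in Control by log2 -0.68 (adjusted p = 1.92e-14) and in PVDF@PDA by -0.38 (3.16e-07). Slc24a5 (-1.0, adjusted p = 0.0148), Lrrc39 (-2.17, 0.00148) and LOC120094192 (-3.82, 0.000390) were lower in PCL@PDA, and in PVDF@PDA lay at 0.47, 0.33 and 0.34 from Control without passing (0.289, 0.687 and 0.762). The Slc24a5 call against Control ended without PCL@PDA replicate 3 (0.0680) or Control replicate 3 (0.135). Unchanged groups that share the PCL@PDA libraries gave 0.5 such genes on average and at most 3, and independent lists would share 1.61 in either direction. The simulated groups held only 1.65 calls on average between PCL@PDA and Control, against 2616 in the data. Independent lists leave out the shared PCL@PDA libraries, so neither value is a chance level for the 4 genes. The count of 4 became 33 with the batch as an added term, 0 without PVDF@PDA replicate 3, 1 without PCL@PDA replicate 3 and 535 without PCL@PDA replicate 1, and Lrrc39, LOC120094192 and Slc24a5 have few reads or an overlapping gene.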

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

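The 8 genes that differed between PVDF@PDA and PCL@PDA are taken up here because the difference between the materials is the question of the study. The tests of explanations in this part were chosen after the result was seen, while leaving out each library was planned. The log2 differences were 1.30 for Best1, 1.47 for Slc24a5, 1.11 for Cacna2d4, 0.49 for Wdr38, 0.29 for Mmp13, -0.37 for Slc39a13, 2.5 for Lrrc39 and 4.16 for LOC120094192.

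For the 5 of these genes that have a tested neighbour, a fixed share of the neighbour's reads would give both genes the same fold change, and 7 of 8 pairs differed by more than 2 SE, among them Best1 and Fth1 (1.30 and 0.02) and Wdr38 and Rpl35 (0.49 and -0.00345). In the remaining pair, Lrtm2 at 0.491 CPM has too few reads to supply Cacna2d4 at 6.08 CPM, so this explanation is unlikely. Gene length bias is unlikely for 7 genes, which stayed called with the length trend removed; Slc39a13 did not (-0.36, adjusted p = 0.0805), although all 8 passed once the batch was added as well. A single PVDF@PDA library remains possible: PVDF@PDA replicate 1 also lay beyond both PCL@PDA libraries in 8 of 8 genes, but genes picked for a difference lean that way, and without PVDF@PDA replicate 3, where 0 genes passed, the log2 difference fell for Best1 (0.82), Slc24a5 (0.87), Cacna2d4 (0.62) and LOC120094192 (2.77) but stayed near its size for Wdr38 (0.44), Slc39a13 (-0.41), Mmp13 (0.23) and Lrrc39 (2.22). Further PVDF@PDA and PCL@PDA libraries would separate a material effect from a library effect on Best1, Wdr38 and Mmp13.

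PCL@PDA replicate 3 stood apart from PCL@PDA replicate 1, and its removal ended the call of 6 of the 8 genes, most at a similar log2 difference (1.39 for Slc24a5, -0.35 for Slc39a13, 0.95 for Cacna2d4). A batch difference shared by the groups is unlikely, because the difference of replicate 3 minus replicate 1 in PCL@PDA correlated across genes at 0.132 at most with that of the other groups. Gene length bias is unlikely, as removing the length trend took away 2.43% of the excess SD (0.207 against 0.181 in PVDF@PDA and 0.187 in Control). A swap with a Control library is unlikely, since PCL@PDA replicate 3 had a first component score of -14.9, beside the other material libraries. That score cannot show whether PVDF@PDA and PCL@PDA libraries were exchanged, which was not tested. The free-text field of the PCL@PDA libraries names the other material. By chi-square per degree of freedom, PCL@PDA replicate 1 lay nearer to the PVDF@PDA libraries (4.47 and 5.38) than to PCL@PDA replicate 3 (10.6). PCL@PDA replicate 3 differed from the PVDF@PDA libraries by 13.0 and 13.3. What set PCL@PDA replicate 3 apart was not resolved.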

How the results depend on the processing

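Between PVDF@PDA and PCL@PDA the count of 8 genes became 59 with the batch as an added term, 22 with that term in a non-robust fit, 42 with that term and the length trend removed and 15 with that term in DESeq2. It was 17 with no filter on low counts, 5 with library totals only, 5 in DESeq2, 0 with limma on log2(FPKM + 1) and 0 on log2(FPKM + 0.1), and 5 genes also had a log2 fold change of at least 1. With 1 library left out it ran from 0 (PVDF@PDA replicate 3) to 827 (PCL@PDA replicate 1). The cause of these shifts was not tested. A library left alone in its group is assumed to vary like those of the other groups.

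For PVDF@PDA against Control the 2042 genes became 1159 and 1164 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), 139 had a log2 fold change of at least 1, and leaving out a library gave 1031 (PVDF@PDA replicate 3) to 2869 (PCL@PDA replicate 3). For PCL@PDA against Control the 2616 genes became 1645 and 1635 with limma, 145 had a log2 fold change of at least 1, and leaving out a library gave 1346 (Control replicate 1) to 3173 (PCL@PDA replicate 1). The shared count of 1519 ran from 797 without Control replicate 1 to 1789 without PCL@PDA replicate 1. The count of 4 genes called in opposite directions between PVDF@PDA and PCL@PDA and between PCL@PDA and Control became 33 with the batch as an added term, and 0 to 535 with 1 library left out.

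Camera called 5, 9 and 8 lists, and with an estimated correlation 0, 0 and 0. The fry test called 0, 4 and 8 lists. With PVDF@PDA against Control it left out the hypoxia-induced genes (adjusted p = 0.0528), the glycolytic enzymes (0.125), the p53 targets (0.0993), the lysosome genes (0.0610) and the neuron markers (0.0572). With PCL@PDA it left out the glycolytic enzymes (adjusted p = 0.0698) and added the neurotrophic factors (0.0460). Between the materials the lists called ran from 0 without PVDF@PDA replicate 1 to 5 without PCL@PDA replicate 1, of which 4 were among those called with all libraries.

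Among named genes the batch term added a call for 13 of 66 genes between the materials, 2 of 99 for PVDF@PDA against Control and 1 of 104 for PCL@PDA against Control. It ended 0 calls and changed no other. With 1 library left out, 8, 17 and 28 of these genes lost their call at least once, and 34, 3 and 1 gained one.

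Some differences that did not pass changed sign. Between the materials, with 1 library left out, Bnip3 ran from -0.0295 to 0.0789, Ca9 from -0.115 to 0.0752, Jun from -0.0269 to 0.0660, Piezo1 from -0.218 to 0.0202, Hmox1 from -0.290 to 0.0421 and S100b from -0.32 to 3.02. Ca9 was at 0.00216 with the length trend removed and 0.00182 with the batch term as well. Against Control, S100b ran from -1.02 to 2.07 with PVDF@PDA and from -2.96 to 1.32 with PCL@PDA, and the neuron marker Syt1 ran from -3.04 to 0.97 with PCL@PDA.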

Other observations

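Pathways drawn from KEGG were tested after the lists had been seen, and they share members with the lists. DNA replication held 13 of 35 genes higher with PVDF@PDA (adjusted p = 0.000418) and 17 of 35 with PCL@PDA (8.43e-06), and glycolysis and gluconeogenesis held 14 and 17 of 45 (0.000933 and 0.000237). The lysosome held 18 and 30 of 108 higher (0.0812 and 0.000139), HIF-1 signalling 18 and 16 of 92 (0.0210 and 0.369) and Rap1 signalling 25 and 28 of 151 (0.0210 and 0.122). NOD-like receptor signalling held 30 of 123 genes lower with each material (0.000592 and 0.0140), NF-kappa B signalling 19 and 21 of 73 (0.00601 and 0.0140) and TNF signalling 22 and 24 of 97 (0.0114 and 0.0372). With the members of the gene lists left out, none of these pathways passed, and DNA replication with PCL@PDA came closest (10 of 28 higher, adjusted p = 0.0606).

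The cell cycle genes split by their role, a division that was not among the lists fixed beforehand. The counts of mitotic and replication members therefore describe the split and do not test it. The prediction for library scaling was written after its result was seen, and those for gene length and for genes outside the list before theirs. All 23 mitotic members of the list were lower with both materials (median log2 -0.60 in each comparison), while 13 (PVDF@PDA) and 14 (PCL@PDA) of 17 replication members were higher and 0 lower (medians 0.46 and 0.57). Library scaling is unlikely to explain this, since 1 factor per library moves both sets alike and the medians differed by 1.06 or more (SE 0.08). Gene length bias is unlikely, because 100% of the called members stayed called with the length trend removed and the batch as an added term. A shift of the cell cycle that reaches genes outside the list remained open, by a test that treats correlated genes as independent: 241 mitotic genes outside it had a median of -0.07 (exact sign test p = 5.62e-06 and 9.64e-08), whereas 81 replication genes had medians of 0.04 and 0.08 (exact sign test p = 0.119 and 0.0448, adjusted over the 4 tests 0.119 and 0.0598).

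The split may reflect a changed mix of phases with both materials, such as more cells in S phase and fewer in mitosis than in Control. Replication genes outside the list, with medians of 0.04 (PVDF@PDA) and 0.08 (PCL@PDA), did not pass the sign test after adjustment. A changed mix could give the difference of 1.06 log2 between the mitotic and replication sets, though which phases changed was not tested. Changed transcription of both sets at an unchanged mix could give the same difference, whereas a change of mitotic genes alone would leave the replication members, with medians of 0.46 and 0.57, unexplained. DNA content and thymidine analogue incorporation in RSC96 cells under the same conditions would separate these, and Ccnb1 and Mcm3 would be the transcripts to follow.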
